A study of Solanum lycopersicum var. cerasiforme with 6 samples.

How the data were processed

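RNA was sequenced from young tomato inflorescences of F3 plants, collected while the largest floral bud was shorter than 2 mm. Each of the 6 libraries held equal amounts of RNA from 2 plants of one genotype, per the labels, giving 3 pools with the derived allele (fw2.3-D) and 3 with the wild-type allele (fw2.3-WT). The genotypes were placed at random in one greenhouse, and the libraries did not keep strand, so reads of overlapping genes on opposite strands cannot be separated. Pools are described as separate groups of plants, so the spread between pools includes plant-to-plant differences, averaged over 2 plants.

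The deposited count files hold whole-number read counts per gene, not normalized, with 34081 rows each. A deposited table of the whole series holds RPKM, reads scaled to gene length and to the total counted reads, in 34075 rows. Cutadapt, STAR and edgeR are named in the submitters' processing notes, without roles or versions. The program that counted the reads and the handling of reads that match several places are not given in the sources used here. The deposited RPKM were compared with the deposited counts gene by gene. Of 24595 genes with counts in 2 or more pools, 24593 gave one whole-number gene length in every pool, within 0.01 base, so the RPKM carry no normalization between pools beyond the total. The 2 exceptions are neighbouring loci on chromosome 2, which have 8 rows in the count files and 1 row each in the RPKM table. What the row suffixes stand for is not stated, and the rows may be near-identical copies that share reads, so values at these loci are uncertain. Their rows were tested as deposited, summed per locus, and replaced by the reads that the RPKM table implies.

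Total counts per pool ran from 22303511 to 28504360. A count of 0 in a pool allows up to 0.105 to 0.135 CPM (counts scaled to the library total), from a floor of 3 counts, which covers counting error only. No 2 pools agreed within sampling noise: the chi-square per gene between pairs of pools ran from 14.1 to 55.2. All value columns were mapped to a pool by name.

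Genes were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, two-sided), with TMM factors, filterByExpr with its minimum count of 10, and genotype as the single term. The filter left 20942 rows, called genes below, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are fw2.3-D over fw2.3-WT, and the standard error (SE) is the log2 fold change divided by the square root of the F statistic. Levels are CPM with TMM factors. The share of calls on each chromosome was tested with a two-sided Fisher's exact test, adjusted over chromosomes. Windows of 50 tested genes in identifier order were scanned for calls and compared with 10000 random placements. The chromosome was read from the identifier, and identifier order was taken as genome order. Neighbouring genes are not independent, so these p-values describe these genes.

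Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. Before the data were examined, 22 lists were fixed. Of these, 17 were defined by words in gene descriptions and could not be filled, because the tables used here pair no description with an identifier. The other 5 were fixed by locus number, from published gene assignments as remembered, and no table used here could be used to check each assignment by identifier: 0 of 34081 identifiers matched the reference gene table of the assembly SLM_r2.1. For 26 list members whose symbol is in that table, the chromosome was that of the identifier in 26, and the order was the same in 65 of 65 pairs on one chromosome. That check covers position only. The lists are therefore described as groups. The files do not pair identifiers with names, so no gene names are given and few identifiers are printed.

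The rule for named genes, also fixed before the data were examined, took called genes with a mean of at least 1 CPM and no overlap between the pools of the genotypes, up to 10 in each direction, the 5 with smallest p on chromosome 2, called members of each list, and all members of the fruit weight list. It took all 5 called genes, of which 3 are given by identifier and the others by chromosome. The fruit weight list is given as a range over its tested members.

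Alternatives were DESeq2 1.42.0, RLE factors, no filter, a filter of 1 CPM in 3 pools, the replicate block, each pool left out, glmTreat at a log2 fold change of 1, a robust fit, other thresholds, and limma on log2(RPKM + 1) and log2(RPKM + 0.1). The windows were also scanned at 25 and 100 genes, and the lists were tested without chromosome 2. Summed rows, reads from the RPKM table, a term for the first pools, the first pools left out, and an unadjusted p under 0.05 were added after seeing the data.

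The gene test was tested on simulated data with the means, dispersions and library sizes of these 20942 genes. It recovered 8% of the genes changed 1.5-fold, 66% at 2-fold, 96% at 4-fold and 98% at 8-fold. The simulation changed 50 genes at each fold, drew genes independently and gave 171 calls, against 5 in the real comparison. An adjusted threshold is stricter where fewer genes change, so these shares may overstate the recovery in the real data. The share of false calls was above the nominal 5%: over 10 further draws the median was 9.17% of calls, with a range of 4.27% to 10.2%. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for the file checks and plots.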

Results

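Transcripts of young inflorescences were counted in tomato F3 progenies that segregated for fw2.3, a quantitative trait locus for fruit weight. The comparison asked which genes differ in expression between plants carrying the derived allele, fw2.3-D, and plants carrying the wild-type allele, fw2.3-WT. There were 3 pools of each genotype, each from 2 plants. The fw2.3-D pools held 25859530, 28504360 and 25094534 counts, and the fw2.3-WT pools held 24570493, 22303511 and 23945933.

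Few genes were called between the genotypes. Of 20942 genes tested with edgeR, 5 were called at an adjusted p under 0.05, of which 4 were higher and 1 was lower in fw2.3-D. Solyc12g010030.3, on chromosome 12, stood at 2675 ± 92.1 CPM (SD, n = 3) in fw2.3-D against 841 ± 159 CPM (SD, n = 3) in fw2.3-WT, 3.18-fold higher. Its log2 fold change was 1.67 (SE 0.168), with an edgeR adjusted p of 0.0178. The tested gene next to it on chromosome 12 rose almost as much, from 962 ± 178 to 2967 ± 289 CPM (SD, n = 3), with a log2 fold change of 1.62 (SE 0.174) and an edgeR adjusted p of 0.0178. These neighbours had similar levels in every pool, and whether they share reads is not known, so their separate values are uncertain. Solyc09g084490.4, on chromosome 9, rose from 44.2 ± 7.97 to 145 ± 36.1 CPM (SD, n = 3), a log2 fold change of 1.71 (SE 0.205, edgeR adjusted p = 0.0388). A gene on chromosome 7 rose from 148 ± 23.2 to 404 ± 51.3 CPM (SD, n = 3), a log2 fold change of 1.45 (SE 0.154, edgeR adjusted p = 0.0178). The gene that fell was Solyc02g090750.4, one of several rows of a locus on chromosome 2. It stood at 1.36 ± 0.141 CPM in fw2.3-D against 7.22 ± 0.485 CPM in fw2.3-WT (SD, n = 3), a log2 fold change of -2.40 (SE 0.232, edgeR adjusted p = 0.0178).

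**Figure D1:**
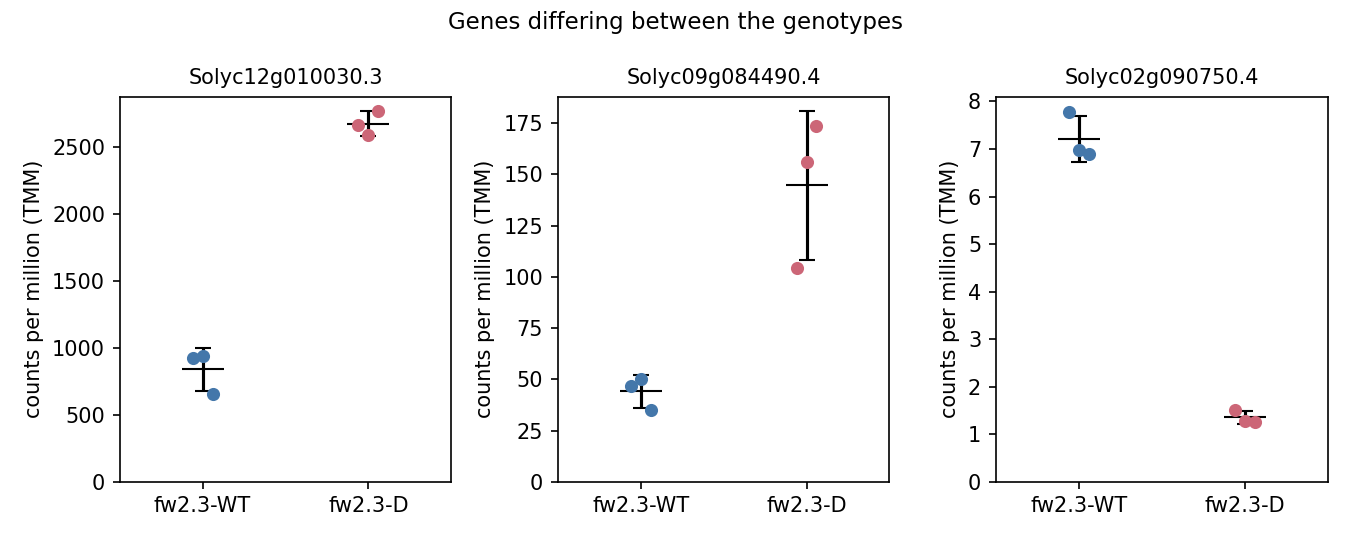
CPM (TMM) of 3 called genes in each pool, with fw2.3-WT in blue and fw2.3-D in red; points are pools, and bars show the mean and SD of 3 pools. In each panel the pools of the genotypes do not overlap; Solyc02g090750.4 is lower in fw2.3-D and the other genes are higher.

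The number of calls changed with the pools used, while the fold changes of the called genes stayed similar. In all 5 the pools of the genotypes did not overlap, so leaving out a pool could not reverse the direction. With each pool left out in turn, the log2 fold change of Solyc12g010030.3 ran from 1.52 to 1.76 and that of Solyc02g090750.4 from -2.49 to -2.35. No gene was called by edgeR without fw2.3-D replicate 2, without fw2.3-D replicate 3, without fw2.3-WT replicate 2 or without fw2.3-WT replicate 3, where 585, 1472, 426 and 604 genes had an unadjusted p under 0.05, and 18 were called without fw2.3-D replicate 1. DESeq2 called 48 genes, including these 5, and limma on log2(RPKM + 1) called 0, with 774 at an unadjusted p under 0.05. Over all tested genes, 746 (3.56%) had an unadjusted p under 0.05, where 1047 would be so by chance, and the pools of the genotypes did not overlap in 9.49%, where chance gives 10%.

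All rows of Solyc02g090750 had lower counts in fw2.3-D, though 1 row alone was called, and the locus listed just before it had higher counts in fw2.3-D. Summed over 5 rows, Solyc02g090750 had 154, 142 and 106 counts in the fw2.3-D pools and 615, 514 and 539 in the fw2.3-WT pools. This was 5.11 ± 0.992 CPM against 23.4 ± 1.87 CPM (SD, n = 3), 4.58-fold lower in fw2.3-D, with a log2 fold change of -2.20 (SE 0.175, edgeR adjusted p = 0.00497). The reads implied by the RPKM table were fewer, at 2.66 ± 0.66 CPM in fw2.3-D against 10.8 ± 1.22 CPM in fw2.3-WT (SD, n = 3). They gave a log2 fold change of -2.02 (SE 0.230, edgeR adjusted p = 0.0300). Why the levels differ is not known, and summed rows may count reads more than once. The preceding locus, summed over 3 rows, had 315, 220 and 247 counts in fw2.3-D and 119, 117 and 149 in fw2.3-WT. Its log2 fold change of 0.89 (SE 0.221) did not pass the test over all genes (edgeR adjusted p = 0.934), although the pools did not overlap. Its rows went different ways: the last of its rows took 5.46% to 11.7% of the counts of the locus in fw2.3-D and 26.9% to 45.3% in fw2.3-WT. Both loci have few counts, and the assignment of reads to their rows is uncertain.

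**Figure D2:**
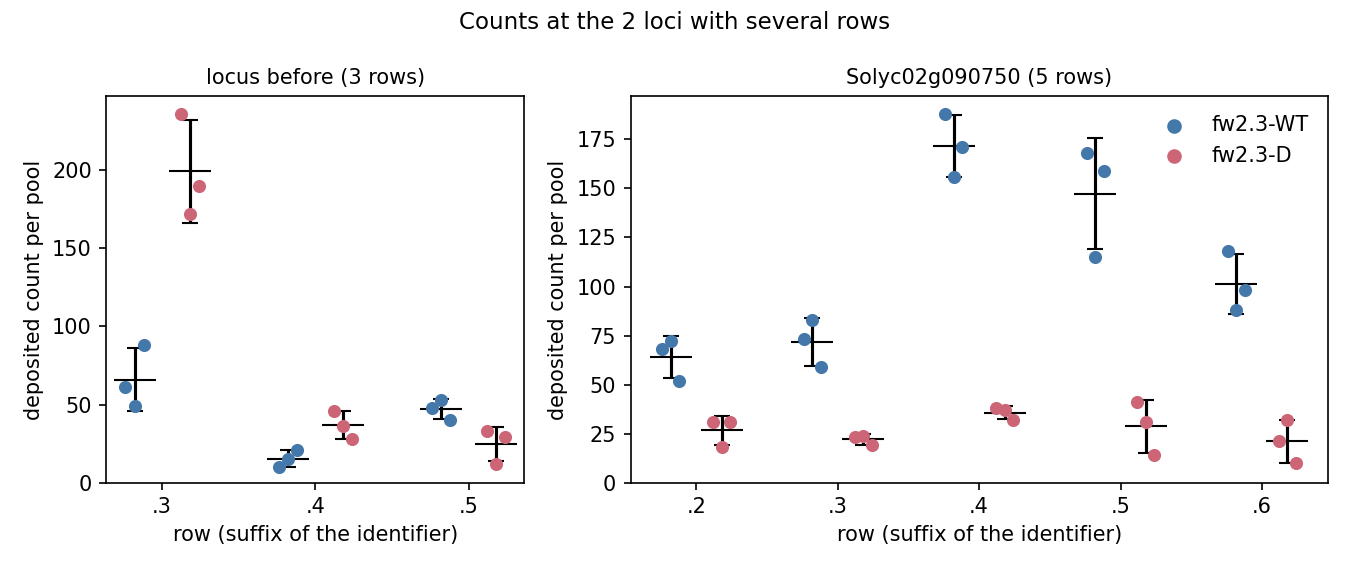
Deposited counts per pool for each row of the 2 loci on chromosome 2 that have several rows, with fw2.3-WT in blue and fw2.3-D in red; points are pools, and bars show the mean and SD of 3 pools. All 5 rows of Solyc02g090750 are lower in fw2.3-D, while the rows of the locus before it go different ways.

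The trait locus is named for chromosome 2, so the share of calls there was compared with other chromosomes. Chromosome 2 held 1 of the 5 calls (20%) and 2302 of the 20942 genes tested, and the difference in share did not pass the test (Fisher's exact test, two-sided, p = 0.441, adjusted p = 1 over chromosomes). Of the 2302 genes tested on chromosome 2, 87 (3.78%) had an unadjusted p under 0.05, against 3.56% of all tested genes (Fisher's exact test, p = 0.551). The 87 include 8 rows of the pair of loci, which may share reads and may not be separate genes. Chromosome 12 held 2 calls (Fisher's exact test, p = 0.0379, adjusted p = 0.492).

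The densest run of calls was the pair of neighbours on chromosome 12. A window of 50 tested genes with 2 of the 5 calls had p = 0.0472 in a permutation test that placed the calls at random. The test took these 2 calls as separate, which is not known, since the neighbours may share reads. The permutation p was 0.0235 with windows of 25 genes and 0.0893 with windows of 100. The place of the run moved with the setting: without a filter it was on chromosome 2, with 4 calls, and with DESeq2 on chromosome 9, with 8 calls. When genes at an unadjusted p under 0.05 were taken instead, with rows summed per locus, the densest window lay on chromosome 9 and held 12 such genes, of which 11 were higher in fw2.3-D, while the 95th percentile of random placements was 9. Solyc09g084490 lay in this run and was its single called gene. With rows as deposited, the densest window lay on chromosome 2 instead and held 16 such genes, which included 8 rows of the pair of loci. With rows summed, chromosome 2 kept a window of 11, a number reached in a share of 0.0033 of the random placements.

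**Figure D3:**
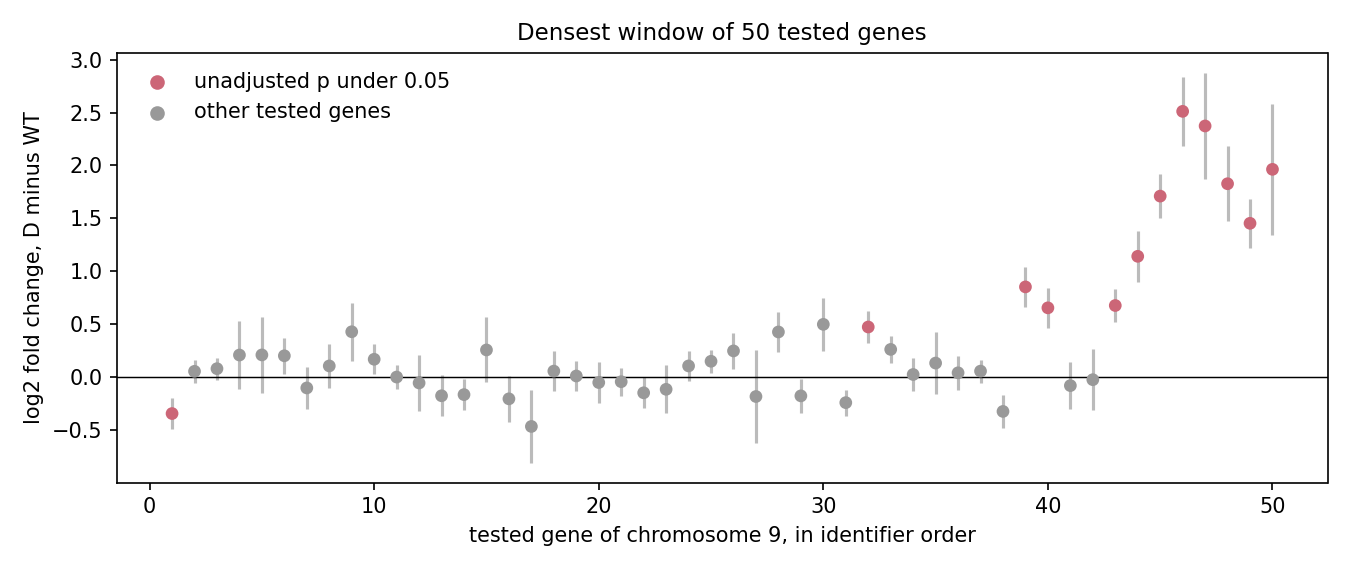
Log2 fold change (fw2.3-D minus fw2.3-WT) of 50 neighbouring tested genes of chromosome 9 in identifier order, with the SE as bars; red points are genes at an unadjusted p under 0.05. Of the 12 red points 11 lie above 0, and most, though not all, of the 12 are at one end of the window.

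Among the gene lists, the inflorescence and meristem identity genes, which set when and where flowers form, passed the test as slightly lower in fw2.3-D. As many lists were called in 6 of the 10 ways to divide the pools into 3 and 3, so chance may account for it. Of 15 members tested, 11 had lower and 4 had higher values in fw2.3-D, with a median log2 fold change of -0.08 and a range of -0.55 to 0.15 (camera adjusted p = 0.0462). The call was lost with an estimated correlation (adjusted p = 0.575), with fry (adjusted p = 0.688) and with DESeq2 statistics. It was also lost without a filter and without chromosome 2 genes, and the count of lists called fell to 0 without fw2.3-D replicate 1, without fw2.3-D replicate 3, without fw2.3-WT replicate 1 or without fw2.3-WT replicate 3. No member was called over all genes, and 0 were called adjusted over the list alone.

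No other list passed the test. Of 10 fruit weight and shape genes, 8 were tested, with log2 fold changes from -0.77 to 0.16 (camera adjusted p = 0.264). The others had too few counts for the filter, so whether they differ is not known. An untested member, listed just before the pair of loci on chromosome 2, had 1, 0 and 4 counts in fw2.3-D. It had 6, 3 and 10 in fw2.3-WT. The 13 tested MADS-box genes, many of which specify floral organs, ran from -0.32 to 0.96 (camera adjusted p = 0.845). The 12 core cell cycle genes lay close to 0, from -0.14 to 0.16, at a median level of 88.5 CPM (camera adjusted p = 0.545). The 5 circadian clock genes, a marker of collection time, ran from -0.34 to 0.06 (camera adjusted p = 0.545). In each of these lists 0 members were called over all genes and 0 adjusted over the list alone by edgeR, and 0 had an unadjusted p under 0.05; DESeq2 statistics called 0 lists. In 4 of the 5 clock genes the first pool of each genotype stood apart from the other pools in the same direction, by more than 0.5 on the log2 scale.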

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

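The term for the first pools, the first pools left out, summed rows, reads from the RPKM table and the unadjusted p were chosen after the data were seen. The count of 5 called genes was 48 with DESeq2, 13 without a filter, 10 with the replicate block, 13 with a term for the first pools and 21 with the first pools left out. It was 0 with glmTreat (51 at an unadjusted p under 0.05), 0 with limma on log2(RPKM + 1) and 0 on log2(RPKM + 0.1) (774 and 746 at an unadjusted p under 0.05), and 0 at an adjusted p under 0.01. With each pool left out it ran from 0 to 18. The cause was not tested. All 5 calls were kept by DESeq2, without a filter, under the block, with the first-pool term and with the first pools left out. No fold change of a named gene reversed, so the lost calls are losses of significance. The replicate numbers did not pair all pools: the deviations of same-numbered pools correlated at 0.357, -0.085 and 0.061. Of 6 pools, 2 correlated best with their own number, and these were the first pools. The first pools also had the lowest chi-square per gene of any pair of pools, 14.1. The share on chromosome 2 was 30.8% without a filter (Fisher's exact test, p = 0.0423), but all 4 of those calls lay in one window that ends in a row of Solyc02g090750, whose rows may share reads, so they may not be separate genes. The share had no value where nothing was called, which includes the RPKM fit. The densest run held 2 calls in windows of 25 and of 100 genes (permutation p = 0.0235 and 0.0893), 4 calls on chromosome 2 without a filter, 8 on chromosome 9 with DESeq2, 3 on chromosome 9 with the replicate block (permutation p = 0.0027), 16 genes at an unadjusted p under 0.05, and 12 of these with rows summed. The smallest p that the placements can give, 0.0001, was reached without a filter, with DESeq2 and with the 16 genes at an unadjusted p under 0.05. The number of lists called, 1, was 0 with DESeq2, 0 without a filter, 0 with an estimated correlation, 0 with fry and 0 without chromosome 2, and ran from 0 to 1 with each pool left out. Across the 4 comparisons and their alternatives, 24 values were labelled the same as reported, 11 stronger and 18 weaker. A count was labelled the same when near the reported one, and a share when its p stayed on the same side of 0.05. For the densest run both were needed. A stronger or weaker value may still point the reported way. At this depth a count of 0 allows up to 0.105 to 0.135 CPM; the simulated recovery was not split by level, so it does not show what depth limits.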

Other observations

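The tests of the chromosome 2 loci, of summed rows as the whole of the chromosome 2 run, of the runs off chromosome 2, of the densest run of calls across splits, of the clock genes, and of leaving out the first pools were chosen only after the result was seen. The 2 genes with an edgeR adjusted p from 0.05 to 0.10 were both higher in fw2.3-D. The one on chromosome 2 had a log2 fold change of 2.08 (SE 0.280, adjusted p = 0.0755), and the one on chromosome 9 had a log2 fold change of 2.51 (SE 0.326, adjusted p = 0.0651) and lies in the run that holds Solyc09g084490.

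The 6 pools can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The genotypes gave 5 calls and the highest of the other splits gave 76, so 2 of the 10 splits gave as many. That split set fw2.3-D replicates 1 and 2 with fw2.3-WT replicate 1 against the other pools, which points to a structure of the samples other than genotype. The share of calls on chromosome 2 was 20% for the genotypes and 7.90% in the only other split with calls (1 of 10 splits as high). The rest had no calls, so they had no share and no run to compare. The counts of splits for the share and the run therefore decide little. The densest run held 2 calls against 3 (2 of 10 splits), and 1 list was called against at most 2 (6 of 10 splits). The count for the lists met what was written in advance for a call that chance could give.

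At the pair of loci on chromosome 2, Solyc02g090750 was lower in fw2.3-D and the locus before it had higher counts. Against a different division of reads among the rows of one locus, the summed log2 fold change lay more than 2 SE from 0 at both loci, but at the locus that changed less, 0.89 (SE 0.221), it did not pass over all genes (edgeR adjusted p = 0.934). A move of reads from one locus to the other would leave their total the same. With rows summed, the log2 fold change of the total, -0.93 (SE 0.162), also lay more than 2 SE from 0. It did not pass over all genes (edgeR adjusted p = 0.311). The summed rows of Solyc02g090750 held 5.11 CPM in fw2.3-D and 23.4 CPM in fw2.3-WT. The reads implied by the RPKM table gave 2.66 and 10.8 CPM. Rows that share reads would weight the total towards that locus, so the total cannot exclude moved reads. A sequence difference between the haplotypes and the reference that is limited to the loci stays open: 44% of the 50 flanking tested genes had a fold change above 0, which decides nothing about the loci themselves. A difference in expression between the alleles may be a candidate explanation and was not separated from it.

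Off chromosome 2, 19 of the 100 genes with the smallest p, of which 4 were called, were followed by another of them, where random draws gave at most 5 and the other splits at most 6, and in 16 of these pairs both genes had higher values in fw2.3-D. On chromosome 2, the window with 16 genes at an unadjusted p under 0.05 included 8 rows of the pair of loci; with rows summed the densest window, of 12 genes, was on chromosome 9, which met what was written in advance for repeated counting of copies, but chromosome 2 kept a window of 11, above the 95th percentile of 9, so copies are not the whole of the run. The split with 76 calls had 17.6% of its genes at an unadjusted p under 0.05, against 3.56% for the genotypes, and it alone gave the highest other counts: 8 in the chromosome 2 window, 13 in the chromosome 9 window and 21 in a window elsewhere (2 of 10 splits as dense). In 2 further splits, with 6.66% and 4.87% of genes at that p, the chromosome 9 window held 10 and 11, so it may vary between pools whatever the genotype. Chromosome segments that still segregate in F3 plants, and are unevenly shared among pools of 2 plants, are a candidate explanation, as are reads shared between neighbouring copies; neither was tested, since no genotypes or sequences were used here.

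The first pools of both genotypes were the pair most alike in chi-square per gene (14.1), and they stood apart in the clock list. In 4 of its 5 members the first pools differed from the others in the same direction in both genotypes, which is consistent with another time of collection, although the labels give no times and the list was where the pattern was noticed. With the first pools of both genotypes left out, 5 of the 5 calls were kept. The log2 fold change of Solyc12g010030.3 was then 1.74, that of Solyc09g084490.4 1.94 and that of Solyc02g090750.4 -2.44. This cannot show whether the calls rest on the first pools. Each genotype has a first pool, so a shift they share is balanced, and the genes were chosen for no overlap in all pools.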
